A study of Mus musculus with 10 samples.

How the data were processed

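Leukemic cells of mouse T cell acute lymphoblastic leukemia (T-ALL) were profiled on 10 oligonucleotide expression arrays, 5 per group. Per the labels, the leukemias were induced by ICN1, the activated intracellular form of NOTCH1. They carried a tamoxifen-inducible Cre recombinase (ROSCreERT2) and floxed alleles of CnB1, the gene of the regulatory B subunit of calcineurin, whose current symbol is Ppp3r1. Secondary recipient mice that had become leukemic were given tamoxifen, which deletes CnB1 (TAM), or its corn oil carrier (OIL). Leukemic cells were over 50% of the marrow and were flow-sorted by a fluorescent marker, and labelled targets were made from 200 ng of total RNA.

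The deposited values are log2 expression values made with RMA, per the submitters' processing notes; the RMA version is not given in the sources used here. RMA corrects background, normalizes arrays by quantiles and summarises the probes of each probe set, so small shifts common to all genes are removed before deposit. The table held 45101 probe sets with values from 1.74 to 14.02. The array medians lay between 5.07 and 5.13 log2 units. Arrays have no read depth, so their number, 5 per group, limits the precision.

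Probe sets were named from the platform annotation: 34958 had 1 gene symbol, 932 had several and were not named, and 9211 had none listed. Control probe sets numbered 64. Of the probe sets with 1 symbol, 34754 matched a gene by Entrez ID in the RefSeq table of assembly GRCm38.p6, used for names only. Each of 18193 genes was represented by its probe set with the highest mean over all 10 arrays. The lowest 30% of genes by that mean, below 4.59 log2 units, were left out, which left 12735 genes.

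TAM was compared with OIL by limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8). Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg over genes), and changes are given as TAM minus OIL. This fit had no block and 8 residual degrees of freedom. The replicate labels 204, 206 and F3 occur in both groups. F3.1 and F3.2 do so only once the number that follows them in the sample names, which differs between the groups, is dropped, as was done here. A fit with the label as a block, with 4 residual degrees of freedom, was set as the alternative. Arrays of the same label deviated together from their group means, with Pearson correlations over genes of 0.76 for 204, 0.75 for 206, 0.58 for F3.1, 0.18 for F3.2 and 0.80 for F3. The pairing comes from the labels and this check, in which every correlation exceeded the limit of 0.1 that had been set. Across the groups, 3 of the 10 arrays, OIL F3.2, TAM F3.1 and TAM F3.2, correlated best with an array of another label. The limit of 0.1 was thus also exceeded by arrays of another label and cannot tell a partner from another array. The pairing is least supported for F3.1 and F3.2, and the block and all counts of pairs rest on it. The labels do not say that each array came from a separate mouse, nor what F3, F3.1 and F3.2 stand for, so p-values measure only the spread between these samples.

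For Ppp3r1, a two-sided exact permutation test over the 10 arrays was added, whose smallest possible p is 0.00794. Gene lists were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation and with fry beside it, over the 31 lists with at least 5 tested members of the 32 that were set. The 32 lists, the main tests, most alternatives and the rule for naming genes were fixed before the data were examined, and what was chosen later is named where it is reported. The rule named Ppp3r1. It then took the 12 risen and 12 fallen genes with the largest changes that moved the same way in all 5 pairs, in each of the fits without and with the block. It also took called members of the fixed lists, up to 4 per direction, and 13 genes chosen beforehand: Cxcr4, Cttn, Notch1, Hes1, Myc, Ptcra, Rcan1, Nfatc1, Igf1r, Bcl2, Cdkn1a, Il7r and Ccr7. Predicted genes without a symbol of their own were passed over.

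The alternatives were the replicate block as a fixed or random term or as 3 label families, no filter or a 50% filter on dim genes, median centring, a further quantile normalization, other ways of choosing a probe set, each probe set on its own, eBayes with trend and robust, array weights, and leaving out each array. On 5 simulated data sets over the same 12735 genes for TAM against OIL, the fit without a block recovered 32.9% of genes changed by 0.5 log2, 87.4% of those changed by 1 and 94.2% of those changed by 2. Of its calls, 0.129% were false. With the block the shares were 80.8%, 98.2% and 100%, with 5.95% false calls. A simulated list shifted by 0.5 was called in 5 of 5 simulations by camera. The simulations gave both arrays of a label the same label effect and drew the noise of each gene independently. These shares therefore hold only for exact pairing and uncorrelated genes. The simulated shift was also larger than the median change of any tested list.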

Results

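Calcineurin is a calcium-dependent phosphatase that activates the NFAT transcription factors in T cells. The comparison asked which transcripts depend on it in NOTCH1-driven mouse T-ALL. Sorted leukemic cells from 5 OIL samples, which kept CnB1, were compared with 5 TAM samples, in which tamoxifen had been given to delete it. Each group held the labels 204, 206, F3.1, F3.2 and F3, with F3.1 and F3.2 shortened by dropping a final number that differed between the groups. Array medians differed by little, between 5.07 and 5.13 log2 units. The beta-actin 3' minus 5' signal was 0.47 ± 0.10 in OIL and 0.47 ± 0.14 in TAM (SD, n = 5, exact permutation p = 0.96). For Gapdh it was 0.12 ± 0.13 and 0.10 ± 0.16 (SD, n = 5, exact permutation p = 0.746).

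The first principal component held 41.9% of the variance and separated the arrays labelled 204 and 206 from those labelled F3, F3.1 and F3.2. The second component held 18.0% and separated TAM from OIL, except that the OIL F3 array, at -6.90, lay among the TAM arrays. The arrays OIL F3.1 and OIL F3.2 were the most alike of all pairs (r = 0.997 over probe sets, SD of the difference 0.19 log2). The next closest pair was OIL F3 and TAM F3 (r = 0.995, SD 0.24). The lowest correlation of any pair was 0.976. Of the sex-linked genes, too few for a list test, Kdm5d was 8.04 ± 0.10 in OIL and 8.12 ± 0.11 in TAM, Eif2s3y was 8.94 ± 0.13 and 8.83 ± 0.17, Uty was 6.16 ± 0.12 and 6.41 ± 0.22, and Xist was 5.51 ± 0.15 and 5.45 ± 0.34 (log2, SD, n = 5).

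**Figure D1:**
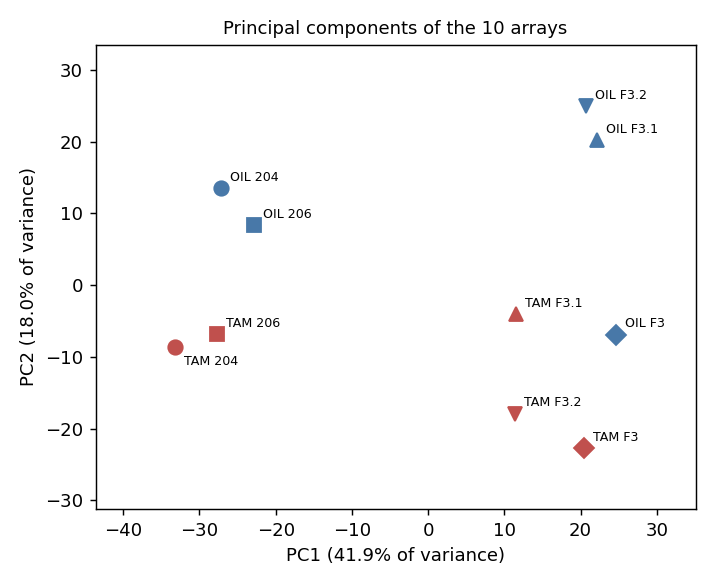
Each point is 1 of the 10 arrays on the first (41.9% of variance) and second (18.0%) principal components of the log2 values of the tested genes, blue for OIL and red for TAM, with a marker for each replicate label. The labels 204 and 206 lie to the left and the F3 labels to the right, and OIL F3 lies among the TAM arrays on the second axis.

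Ppp3r1, the deleted gene, was read by 2 probe sets annotated to it alone. The dimmer probe set was 5.32 ± 0.58 log2 units in OIL and 3.26 ± 0.21 in TAM (SD, n = 5), a difference of -2.06 or 4.17-fold. OIL arrays lay between 4.49 and 6.04 and TAM arrays between 3.02 and 3.59, below the limit of 4.59 used for dim genes. All 5 pairs were lower in TAM, and the two-sided exact permutation p of 0.00794 is the smallest that 5 against 5 arrays can give. The brighter probe set, which represented the gene by the rule, was 9.80 ± 0.09 in OIL and 9.67 ± 0.04 in TAM, a difference of -0.12 that was lower in 5 of 5 pairs (exact permutation p = 0.0238). In limma it did not pass (adjusted p = 0.438). Where either probe set lies relative to the deleted exons was not determined here, and a probe set outside them would not check the labels.

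**Figure D2:**
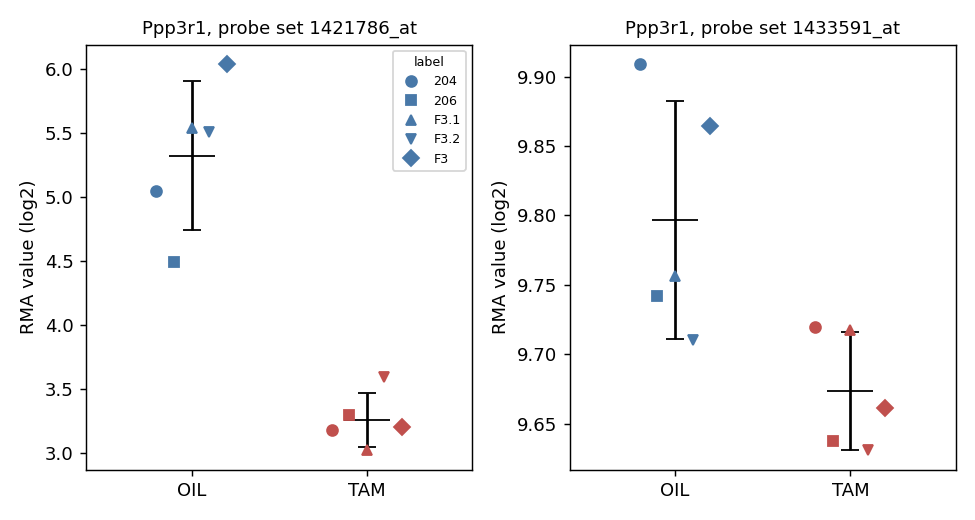
Log2 RMA value of the 2 Ppp3r1 probe sets in OIL (blue) and TAM (red), with 1 point per array, marked by replicate label, and the mean ± SD of 5 arrays in black. The vertical axes differ and do not start at 0; in the left panel, of the dimmer probe set, every TAM array, at most 3.59, lies below every OIL array, at least 4.49.

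Tamoxifen-treated leukemias had higher transcripts of the matrix protease Mmp9, the orphan nuclear receptor Nr4a1, induced by antigen receptor signalling, and the connexin Gjb2. Mmp9 rose by 3.92 log2 units or 15.2-fold, from 5.28 ± 0.20 to 9.20 ± 1.31 (SD, n = 5, limma adjusted p = 0.0159). Its other probe set differed by 3.69. The OIL value lay close to the median of all probe sets, so the fold is uncertain in size. Nr4a1 rose by 2.50, from 6.73 ± 0.67 to 9.22 ± 0.11 (adjusted p = 0.00513), and Gjb2 by 2.37, from 6.70 ± 0.13 to 9.06 ± 0.43 (adjusted p = 0.000614). The largest fall was that of Trnp1, a nuclear protein of neural progenitors, which fell by 4.34 or 20.3-fold, from 10.60 ± 0.70 to 6.26 ± 1.29 (adjusted p = 0.0159), and by only 2.22 with the mean of its 2 probe sets, where it was still called. Ephx1, the microsomal epoxide hydrolase, fell by 2.12, from 6.67 ± 0.39 to 4.55 ± 0.11 (adjusted p = 0.000614). Each of these moved the same way in 5 of 5 pairs, as the naming rule required.

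Further risen genes were Dusp5, a phosphatase of nuclear ERK (1.35), Neto2 (1.26), Cdyl2 (1.21), Hivep1 (1.20), the insulin receptor substrate Irs2 (1.11), the TGF-beta target Pmepa1 (1.06), the Rap activator Rasgrp2 (1.02), the cAMP phosphodiesterase Pde4d (0.95) and the lymphoid transcription factor Irf4 (0.92). Further fallen genes were Frat2, an inhibitor of GSK3 (-1.66), the connexin Gjc1 (-1.35), the ubiquitin ligase Trim2 (-1.18), Rilpl2 (-0.94), Stard9 (-0.92), the kinase Rps6ka5 (-0.83), Ccdc162 (-0.77), the fucosyltransferase Fut8 (-0.73), the protein kinase A inhibitor Pkig (-0.67) and Tnnt1 (-0.65). Other probe sets differed by -0.11 to 0.05 for Fut8, 0.23 to 0.98 for Cdyl2, 0.46 to 0.95 for Rasgrp2 and 0.36 for Irf4. With the mean of all probe sets, limma no longer called Fut8 (-0.26, adjusted p = 0.222), Cdyl2 (0.70, 0.131), Pde4d (0.46, 0.126), Irf4 (0.64, 0.118), Stard9 (-0.66, 0.0791), Gjc1 (-1.35, 0.078), Pkig (-0.59, 0.072), Irs2 (1.11, 0.067) or Pmepa1 (0.79, 0.0649). Irs2 has 1 probe set, so its own values did not change in that setting, and the other probe set of Gjc1 differed by -1.35 as well. In all, limma called 60 of 12735 genes, 38 higher and 22 lower in TAM. Of them, 15 changed over 2-fold, 10 up and 5 down. At an unadjusted p under 0.05 there were 1657 of the 12735 genes, and 2848 in the fit with the block. Counts of list members at that limit are to be read against these shares. Each of the 60 moved the same way in all 5 pairs, and so did 2785 of all tested genes (21.9%, against 6.25% by chance).

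With the replicate label as a block, 431 genes were called, 210 higher and 221 lower, which included all 60. The count without the block depended on single arrays. It was 8 without OIL F3.1, 10 without OIL F3.2, 19 without OIL 204, 24 without TAM F3.1, 28 without TAM 206 and 36 without TAM 204. It was also 10 when OIL F3.1 and OIL F3.2 were averaged and used as 1 sample, an alternative chosen after the data were seen. Of the 29 named genes called without the block, Nr4a1, Gjb2, Ephx1, Trim2, Rilpl2, Fut8 and Adgre5, described below with its list, kept their calls whichever array was left out. Mmp9, Trnp1 and Rps6ka5 lost theirs without OIL F3.1 (limma adjusted p = 0.0692), without OIL F3.2 (0.0506) and with these 2 arrays averaged (0.0586). Each of the others also lost its call in all 3 settings.

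**Figure D3:**
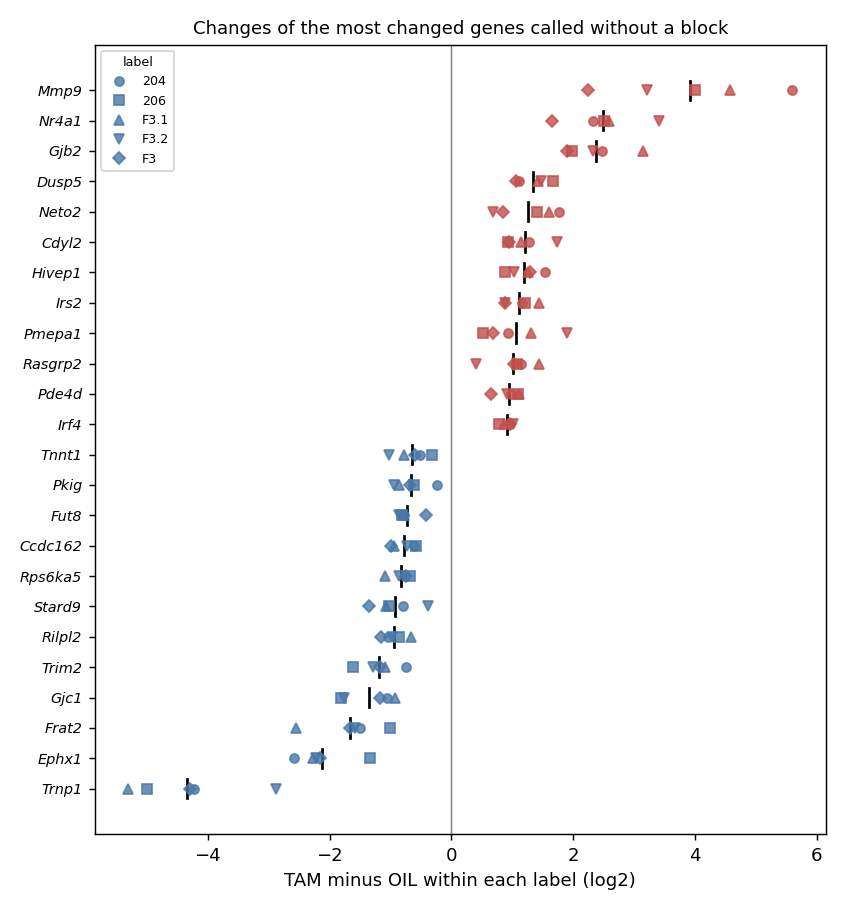
TAM minus OIL difference (log2) within each replicate label for the 12 risen genes (red) and 12 fallen genes (blue) with the largest changes called without a block, with the mean change as a black bar. All points of a gene lie on 1 side of 0, as the rule that chose these genes required. Mmp9 and Trnp1, at 3.92 and -4.34, have the largest mean changes.

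The fit with the replicate block called further genes with large changes. The fatty acid carrier Fabp4 rose by 3.38, from 7.14 ± 0.91 to 10.52 ± 1.42 (SD, n = 5, limma adjusted p = 0.00627 with the block and 0.0575 without it). E-cadherin (Cdh1) rose by 2.91 (0.0171 and 0.0617), and the cell cycle inhibitor Cdkn1a (p21) by 1.78, from 6.64 ± 0.59 to 8.42 ± 0.61 (0.00356 and 0.0511). Also called only with the block, among risen genes, were the collagen Col4a2 (2.61, from 4.56 in OIL, below the limit for dim genes, so its size is uncertain), Tsc22d1 (2.49), the prostaglandin D synthase Hpgds (1.98), Ttyh2 (1.95), the enolase Eno3 (1.80) and the receptor Erbb3 (1.79). Fallen ones were the lipocalin Apod (-2.76), the transcription factor Nfib (-2.55), the ceramide synthase Cers4 (-2.25), Bambi-ps1 (-2.05), Cym (-1.87), the cystatin Cst7 (-1.82), Pdlim4 (-1.77), the kinase anchor Akap12 (-1.74) and Rbpms (-1.73). Each of these moved the same way in 5 of 5 pairs, as the naming rule required. Col4a2 was 4.56 in OIL, below the limit for dim genes, so the size of its change is uncertain. Fabp4, Cdh1, Cdkn1a, Col4a2, Apod, Nfib, Cers4 and Akap12 were each also called in 1 fit without the block that left out an array. Other probe sets differed by -2.26 to 0.05 for Nfib, 0.53 to 3.18 for Fabp4, 0.33 to 2.60 for Tsc22d1, 0.23 for Ttyh2 and -1.38 for Apod. The mean of all probe sets gave smaller changes for Fabp4 (2.11), Nfib (-1.56), Tsc22d1 (1.19), Ttyh2 (1.09) and Erbb3 (0.86). The blocked count was 87 without the pair F3.1, 146 without 204, 153 without F3 and 184 without 206.

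Among 12 tested calcineurin subunits and regulators, 1 rose and none fell. The riser was the NFAT family member Nfatc2 (0.71, limma adjusted p = 0.0323, higher in 5 of 5 pairs), whose 3 other bright probe sets differed by -0.13 to -0.04 and whose call was lost with the mean of all probe sets (0.11, adjusted p = 0.489). The feedback inhibitor Rcan1 (-0.28) and Nfatc1 (-0.22) did not pass. Of 19 NFAT-dependent activation genes, Nr4a1 and Irf4 rose. The inhibitory receptor Pdcd1 (PD-1) fell with the block (-1.38, limma adjusted p = 0.0385 against 0.115 without). Among 20 negative regulators of T cell receptor signalling, 0 were called without the block, with 5 at an unadjusted p under 0.05, and 3 fell with it: Pdcd1, the phosphatase Ptpn6 (SHP-1, -0.88) and the adaptor Sla (-0.66), one of whose other probe sets differed by 0.16. Of 23 genes of the receptor complex and its proximal signalling, 0 were called without the block, with 5 at an unadjusted p under 0.05. With it, Tcra (1.02) and the costimulator Cd28 (0.56) rose and the adhesion receptor Cd2 fell (-0.999).

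Adjusted over the list alone, these lists gave without the block 1 riser for calcineurin, 3 risers and 1 faller for NFAT-dependent genes, 0 and 3 for negative regulators, and 1 and 1 for the receptor complex. No shift of a whole list passed in camera (adjusted p = 0.834, 0.467, 0.906 and 0.161). The negative regulators had a median of 0.05 and a mean of -0.04, and camera placed them up where fry placed them down.

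Immediate early and stress genes, which respond to signalling within minutes, were higher in TAM for 21 of 25 members, with a median difference of 0.25. Dusp5 and Junb (0.53, limma adjusted p = 0.0479, and 0.0649 with the mean of all probe sets) rose. Junb has 1 probe set, so its own values did not change in that setting. With the block 4 more rose: the ERK phosphatase Dusp1 (0.74), Zfp36l1 (0.66), Ier2 (0.64) and the mRNA decay factor Zfp36 (0.92). Without the block 8 rose and 0 fell when adjusted over the list alone, and with it 9 rose and 2 fell. Camera called the list (adjusted p = 4.27e-07), but not with an estimated correlation (adjusted p = 0.144). Fry gave an adjusted p of 0.0395. Klf4 went the other way, at -1.28, without passing (adjusted p = 0.379).

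Genes of the unfolded protein and amino acid response were higher for 21 of 25 members (median 0.21), of which 0 were called without the block and 4 had an unadjusted p under 0.05. With the block, Chac1, a glutathione-degrading enzyme induced by ATF4, rose by 0.97 and Cebpb fell by 0.83. Of 20 cholesterol synthesis genes, 14 were higher (median 0.24), and Srebf2, the transcription factor of the pathway, rose by 0.55 (limma adjusted p = 0.0269, 5 of 5 pairs), with 0.13 at its other probe set and no call with the mean of both (0.34, adjusted p = 0.21). Of 27 G1/S genes, 20 were higher (median 0.08). None passed without the block (limma, 0 called, 7 at an unadjusted p under 0.05). Cyclin D3 (Ccnd3, 1.08) and thymidylate synthase (Tyms, 0.64) rose with it, though the other probe sets of Ccnd3 differed by -0.30 to 0.44 and that of Tyms by 0.26. Of 29 G2/M genes, 20 were higher (median 0.06), with 0 called and 4 at an unadjusted p under 0.05. In these 4 lists 1, 1, 3 and 0 members rose and 0 fell without the block, adjusted over the list alone. With it the first had 4 risen and 1 fallen, and the others did not change.

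Camera called all 4 lists as higher, at adjusted p = 3.82e-05 for the unfolded protein response, 0.00155 for cholesterol synthesis, 6.42e-05 for G1/S and 0.0425 for G2/M. With an estimated correlation none was called (adjusted p = 0.745, 0.783, 0.783 and 0.792). The G2/M call was lost without OIL F3.1 (adjusted p = 0.191), OIL F3.2 (0.275), TAM 204 (0.391), TAM 206 (0.163) or TAM F3 (0.0536), and the cholesterol call without OIL 204 (0.072). Of the 31 lists camera called 5, against 9 without OIL F3 and 8 without TAM F3.1. Glycolysis genes were lower for all but 2 of 17 members (median -0.19). With the block, the glucose transporter Slc2a3 rose (0.74, with 0.31 to 0.80 at its other probe sets) and the kinase Pdk1 fell (-0.56, with -0.48 to -0.20). Adjusted over the list alone, 1 glycolysis gene rose and 3 fell without the block, and 1 rose and 6 fell with it. Camera called the list as lower with the block (adjusted p = 0.02 against 0.057 without, and 0.661 with the block and an estimated correlation). It also called it in 3 of the fits without the block that left out 1 array.

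Thymocyte development genes were tested for 31 members. Ets2 rose (0.87, limma adjusted p = 0.0375, and 0.072 with the mean of all probe sets, 5 of 5 pairs), and with the block the heat-stable antigen Cd24a also rose (0.50). The factors Tox (-1.02), Ikzf3 (-0.75, with -0.44 to 0.58 at its other probe sets) and Ikzf1 (-0.34) fell with the block. Of 17 NOTCH targets, 0 were called without the block and 4 had an unadjusted p under 0.05. The feedback regulator Nrarp rose (0.41) and Cdk6 fell (-0.52) with it. Notch1 (0.23), Hes1 (0.30), Ptcra (0.17), Igf1r (0.74, with -0.0039 to 0.90 at its other probe sets), Il7r (-0.51) and Myc (-0.06) did not pass in either fit. Whether the Notch1 probe set also reads ICN1 transcripts was not determined here. None of 29 MYC targets and ribosome biogenesis genes was called in either fit (limma, 0 and 1 at an unadjusted p under 0.05 without and with the block). Adjusted over the list alone without the block, 2 thymocyte genes rose and 2 fell, 2 NOTCH targets rose and 1 fell, and 0 MYC targets did either. The 3 list medians were 0.04, 0.12 and -0.06, and camera called none (adjusted p = 0.284, 0.125 and 0.819).

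Of 25 chemokine receptor, homing and adhesion genes, the adhesion receptor Adgre5 (CD97) rose by 0.87, from 8.91 ± 0.16 to 9.79 ± 0.11 (SD, n = 5, limma adjusted p = 0.00513, 5 of 5 pairs), and Spn (CD43) fell with the block (-0.41). The chemokine receptors Cxcr4 (-0.08) and Ccr7 (0.25) did not pass. Of 31 genes of the actin cytoskeleton and receptor trafficking, 0 were called in either fit, with 2 and 8 at an unadjusted p under 0.05 without and with the block. Cortactin (Cttn) was 7.56 ± 0.84 in OIL and 6.66 ± 1.41 in TAM, lower in 4 of 5 pairs (-0.90, with -1.12 to 0.04 at its other probe sets, adjusted p = 0.609, and 0.0866 with the block). Adjusted over the list alone without the block, 1 homing gene rose and 0 fell, and 0 actin genes did either. The medians were 0.0031 and -0.0071, the means 0.01 and -0.08, and camera called neither list (adjusted p = 0.467 and 0.884).

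Of 22 p53 targets, Ephx1 fell, and Cdkn1a rose with the block. Among 19 BCL2 family members and caspase inhibitors the death promoter Bad fell with the block (-0.28), and Bcl2 itself (0.10) did not pass. The kinase Pim1 (0.57) rose with the block among 28 cytokine receptor and JAK-STAT genes, Gbp2 (0.74) among 21 interferon response genes, Etv6 (0.49) among 19 T-ALL transcription factor oncogenes and Mef2a (0.69, with 0.06 to 0.89 at its other probe sets) among 23 calcium signalling genes. Oxidative phosphorylation, lysosome and oestrogen receptor target lists had 0 called members in either fit. At an unadjusted p under 0.05 without the block they had 2 of 22, 5 of 23 and 3 of 16, against 1657 of all 12735 genes. Camera called none of these 9 lists (adjusted p = 0.288, 0.885, 0.612, 0.211, 0.906, 0.28, 0.153, 0.476 and 0.838 in the order named, from p53 targets to oestrogen receptor targets).

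Adjusted over the list alone without the block, 2 p53 targets rose and 1 fell, 2 cytokine genes rose and 1 fell, 1 interferon gene rose, and 0 members of the BCL2, T-ALL factor, calcium, oxidative phosphorylation, lysosome and oestrogen lists passed. List medians were 0.05 for p53, -0.05 for the BCL2 family, 0.0017 for interferon, 0.01 for calcium, -0.06 for oxidative phosphorylation, -0.06 for lysosome and -0.06 for oestrogen receptor targets. The cytokine list had a median of -0.01, a mean of 0.07 and a camera direction of up. The T-ALL factor list had a median of -0.03, a mean of 0.01 and a camera direction of down. With the block, camera placed it and the BCL2 family up.

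Markers of other marrow cells were examined in the sorted cells. Neutrophil lineage markers were higher for 10 of 12 members (median 0.23, mean 0.61), but only Mmp9 passed. S100a8 was 7.22 ± 1.55 in OIL and 8.15 ± 1.42 in TAM, and S100a9 6.56 ± 1.43 and 7.44 ± 1.42 (SD, n = 5), each higher in 3 of 5 pairs (limma adjusted p = 0.692 and 0.702). Camera called this list as higher with the block (adjusted p = 0.0153 against 0.0532 without, and 0.661 with the block and an estimated correlation). It also called it in 5 of the fits without the block that left out 1 array. Monocyte and macrophage (14 tested, median 0.04), erythroid (11, -0.08), B lineage (8, -0.01 with a mean of 0.09 and a camera direction of up), megakaryocyte (8, -0.03), stromal and endothelial (10, 0.02, camera up and fry down) and cytotoxic lymphocyte markers (9, 0.12) had 0 called members in either limma fit. At an unadjusted p under 0.05 without the block they had 2, 1, 1, 1, 0 and 2. Of all marker lists, 1 cytotoxic marker and Mmp9 rose without the block, adjusted over the list alone. Camera called none of these 6 lists (adjusted p = 0.476, 0.819, 0.467, 0.801, 0.906 and 0.253 in the order named).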

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

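The tests of neutrophil-lineage cells, of handling stress and of tamoxifen itself, and the look at probe sets not named here, were chosen only after the results they concern had been seen.

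In 8 of 172 groups of 5 arrays, 1 array stood apart from the other 4 by Dixon's test, against 8.6 by chance at 1 in 20. Of these, 5 were on OIL 206: Mmp9 at 4.92 (others 5.34 to 5.41), Frat2 at 7.14 (8.04 to 8.27), Tnnt1 at 7.35 (7.59 to 7.68), Cdkn1a at 7.67 (6.26 to 6.51) and Ikzf1 at 11.34 (11.99 to 12.21). On OIL F3, Cdyl2 was 8.14 (others 7.28 to 7.37) and Fabp4 was 5.59 (7.22 to 7.85). On TAM F3.1, Ptcra was 10.76 (others 11.36 to 11.60). Among the 4889 tested probe sets without a listed gene, which the comparisons left out, limma called 2, and 57 with the block. The larger change was a rise by 3.71, from 5.23 ± 0.77 to 8.94 ± 0.65 (SD, n = 5, limma adjusted p = 0.00793, and 0.0168 with the block), in 5 of 5 pairs. The other fell by 0.75 (adjusted p = 0.00793, 5 of 5 pairs).

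Of 100 splits of the 10 arrays into 5 and 5, drawn from 126, 3 gave at least 60 called genes, the real one included. The other splits gave 361 and 260. Both set the arrays of 204 and 206 with 1 TAM array of an F3 label against the rest. This points to a structure of the samples along the labels. The 100 splits were drawn without regard to the pairs, so the share of 3 in 100 does not exclude chance. Among the 16 splits that part all 5 pairs, limma called 60 genes without the block and 431 with it in the real one, and at most 0 in the others with either fit, but 16 are too few for a share under 0.05. Whether the changes follow the loss of CnB1 or tamoxifen itself cannot be told apart, because every TAM array had both. Of 16 tested oestrogen receptor targets, 0 were called by limma in either fit. There were 3 and 4 at an unadjusted p under 0.05 without and with the block. Adjusted over the list alone, 1 rose with the block. This excludes no action of the drug, through the oestrogen receptor or otherwise.

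The rise of Mmp9 may reflect neutrophil-lineage cells left in the sorted TAM samples, since Mmp9 is on the list of their markers. For that, a rise of the other 11 tested markers by at least 1 log2 unit was set as the bound. Their median difference, averaged over the 5 pairs, was 0.22 (SE 0.15, upper bound 0.52 at 2 SE). The bound was set after the median of the list had been seen, so a value under it decides nothing. The values show that these markers, by their median, rose by less than Mmp9. In the pairs 206 and F3.1 their median was -0.06 and -0.21, while Mmp9 rose by 4.00 and 4.58. In 204, F3.2 and F3 it was 0.46, 0.48 and 0.46. As far as these markers show, this argues against such cells as the source of the Mmp9 rise in 206 and F3.1. S100a8 and S100a9, among the most abundant transcripts of these cells, were higher by 0.94 ± 0.82 and 0.87 ± 0.79 (SE), and the sort by a leukemia marker is meant to remove such cells. For 204, F3.2 and F3, such cells stay open for a part of the rise. A change within the leukemic cells themselves stays open as a hypothesis in all pairs, with tamoxifen as above.

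The rise of immediate early genes may come from handling or sorting that differed between the groups. The 10 tested members that handling and heat induce had a median difference, averaged over the 5 pairs, of 0.59 (SE 0.085). They belong to the list whose rise was already known, and the bound of 0.25 was about its median, so this value decides nothing and handling stays open. The heat shock members Hspa1b (-0.01) and Dnajb1 (0.12) moved little. A change in signalling after CnB1 loss was not tested apart from it.

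Camera called 5 gene lists in the real split. Of 100 splits, 55 called at least as many, with 13 as the highest of the others, so chance cannot be excluded for that count. Among the 16 splits that part all pairs, the highest of the others was 10.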

How the results depend on the processing

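The mean of OIL F3.1 and OIL F3.2 as 1 sample and every alternative of the blocked count were chosen only after the data had been seen. The pairing with the replicate label as a replicate block moved the count of genes changed between TAM and OIL from 60 to 431. It was 227 with 3 label families, 728 with a random block and 242 with array weights, each holding all 60. It was 26 with the mean of all probe sets, 33 with the probe set of largest interquartile range, 32 with every probe set on its own, 10 with the averaged OIL arrays and 8 to 54 when each array was left out. The count of genes changed with the replicate block, 431, was 805 with array weights and 87 to 436 without each pair. Gene lists shifted between TAM and OIL numbered 8 without a filter, 0 with an estimated correlation (2 at an unadjusted p under 0.05), 1 with fry and 4 to 9 without each array. The Ppp3r1 level in TAM and OIL passed with the mean of all probe sets (-1.09) and with the set of largest interquartile range (-2.06, adjusted p over all alternatives 0.0104 to 0.611), because these take in its dimmer probe set. Except where given beside a result, the block changed no call of a named gene or list. The block moved the risen and fallen members, adjusted over the list alone, to 2 and 4 for negative regulators, 3 and 2 for the receptor complex, 2 and 3 for thymocyte genes, 5 and 1 for NOTCH targets, 3 and 1 for p53 targets, 0 and 1 for the BCL2 family, 2 and 2 for homing genes, 5 and 3 for cytokine genes, 2 and 0 for interferon genes, 2 and 1 for calcium genes, 1 and 0 each for T-ALL factors, oestrogen receptor targets and stromal markers, and 1 and 1 for cytotoxic markers. Of 29 named called genes, 6 kept their calls in every alternative that tested them, and 198 of 635 alternatives lost a call with 0 reversed. Uncalled genes reversed in 7 of 1226 and were newly called in 146. The log2 change of Cxcr4 ran from -0.14 to 0.0080 without each array, that of Bcl2 from -0.053 to 0.17, and that of Myc from -0.19 to 0.030. Array weights gave -0.17 for Cxcr4 and 0.18 for Myc, and the probe set of largest interquartile range gave 0.38 for Bcl2. The mean of all probe sets gave -0.20 for Ikzf3, 0.41 for Ccnd3, 0.19 for Tyms, -0.33 for Pdk1 and -0.44 for Cttn, and the set of largest interquartile range -0.44 for Ikzf3 and -0.23 for Spn. Cebpb was -0.48 without TAM 206, Cttn ran from -1.47 to -0.56 without each array, and Il7r from -0.77 to -0.32. Leaving out arrays means fewer samples, and otherwise the cause was not tested. Other scalings moved no single array value of any probe set by over 0.091. Tests of label family by treatment cannot tell whether the changes differed between families. The families 204 and 206 held 1 array in each group, so the residual spread came from F3, F3.1 and F3.2 alone. That spread includes any difference between these 3 labels. Signal over background limits the dimmer Ppp3r1 probe set and other genes near 4.59, whose changes are uncertain in size. Such genes were Col4a2 in OIL and Ephx1, Nfib, Cst7 and Apod in TAM. Mmp9, Tcra, Chac1 and Hpgds in OIL lay close to the array medians, so the same limit may hold for them. It may also hold for Pdcd1, Rbpms, Stard9, Ccdc162 and Cers4, which lay close to these medians in TAM.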

Other observations

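The 4 lists of the next 2 paragraphs and the test of p53 were chosen only after the called genes had been seen, while the list of p53 targets was fixed before. Some members of the 4 lists were included because they had been called, so their p-values, adjusted over these 4, are not independent evidence of direction.

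Genes of fatty acid beta-oxidation, the mitochondrial breakdown of fatty acids, were lower in TAM for 19 of 19 tested members (median -0.21). In the fit with the replicate block 5 fell: Acaa2 (-0.87), Eci2 (-0.47), Acadvl (-0.40), Hadh (-0.37) and Acat1 (-0.31). Without the block the lowest adjusted p in limma was 0.0886, for Eci2, lower in 5 of 5 pairs. Camera with an estimated correlation gave adjusted p = 0.0295, and 0.0485 with the block. Genes of the ciliary transition zone and intraflagellar transport were lower for 21 of 23 (median -0.19). With the block B9d1 (-0.63), Kif3a (-0.56), Tmem107 (-0.37), B9d2 (-0.36) and Tmem237 (-0.34) fell and Ahi1 (0.52) rose, but the list did not pass with an estimated correlation (adjusted p = 0.0669, and 0.0821 with the block).

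Feedback genes of ERK signalling were higher in TAM for 9 of 12 members (median 0.45). Dusp5 rose in both fits, and Dusp4 (1.23) and Phlda1 (0.53) with the block. Camera with an estimated correlation gave adjusted p = 0.0198, and 0.0799 with the block. The list shares at least Dusp5 with the immediate early and stress genes, whose rise was already known, so it is not separate evidence. For those genes the same test, adjusted over the fixed lists, gave 0.144 without the block. The adjusted p-values come from different sets of lists and cannot be ranked. Handling, left open for the immediate early genes, was not tested here and stays open too. TGF-beta feedback and target genes were higher for 12 of 17 (median 0.16). Pmepa1 rose in both fits, and the corepressors Skil (0.98) and Tgif1 (0.42), the signal transducer Smad3 (0.42) and Ldlrad4 (0.58) with the block. For the TGF-beta list, camera with an estimated correlation gave adjusted p = 0.0198, and 0.0485 with the block.

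A hypothesis was that Cdkn1a rose through p53, which Cre recombinase may activate by damaging DNA. The other 21 tested p53 targets had a median difference, averaged over the 5 pairs, of 0.035 (SE 0.034), under the 0.5 set as a bound, but they went both ways, and p53 need not raise all of them. Adjusted in limma over the list alone, Plk2 rose (1.48, adjusted p = 0.0307, and 0.0205 with the block) and Mdm2 passed with the block (0.21, adjusted p = 0.0491), while Ephx1 fell by 2.12. These values show no broad rise of p53 targets and leave open both p53 and other regulation of Cdkn1a.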
